A study of Mus musculus with 10 samples.

How the data were processed

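RNA was taken from mouse hearts labelled control or knockout for Prdm16, collected at 2 ages, and was sequenced, per the labels. The 3-month libraries were strand-specific poly(A) libraries made with the NEBNext Ultra II Directional kit, and the 12-month libraries came from the Genome Institute of Singapore, per the labels. The deposited values are FPKM (fragments scaled to transcript length and to mapped fragments), made by the authors, with 1 table per age, 1 column per library and no counts. FastQC, TopHat2 2.1.0, STAR 2.5.1b and Cufflinks 2.1.1 and the build names mm10 and GRCm38 are named per the submitters' processing notes, and their roles and order are not given in the sources used here. Whether values were also scaled between libraries is not given in the sources used here. The name of the 12-month table says that outliers were left out, without saying how. The ages differ in table and library preparation, so levels were tested only within an age.

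The 3-month table held 46855 rows, of which 69 repeated an identifier and were summed, giving 46786 genes, and the 12-month table held 46977 genes. Identifiers were versioned Ensembl gene identifiers, matched to GENCODE mouse release M21 (GRCm38) for symbols, biotypes and coordinates. The identifier was found for 46297 and 46484 genes and not for 489 and 493. Of the 12-month genes, 191 were not analysed at 3 months, 187 of them on chromosome 8 between 119910360 and 124345724, a stretch that includes Acta1. No column of another sample was used or left unassigned.

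Groups and replicate numbers came from the labels, with 3 control and 3 knockout libraries at 3 months and 2 and 2 at 12 months. The unit is normalised, so no count model was used as the main test. Genes with a mean of at least 1 FPKM over the libraries of an age were tested, 12200 at 3 months and 13179 at 12 months, on log2(FPKM + 1). The test was limma 3.58.1 in R 4.3.3, with 1 contrast of knockout minus control per age, empirical Bayes moderation with a trend and Benjamini-Hochberg adjustment, and genes under an adjusted p of 0.05 were called. The difference between ages was an interaction contrast over all 10 libraries with 4 group means and the 11580 genes tested at both ages. Residual degrees of freedom before moderation were 4 at 3 months and 2 at 12 months.

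Gene lists (40, fixed before the data were examined) covered cardiac stress, contraction, ion handling, metabolism, mitochondria, signalling, markers of the cell types a dissected heart can hold, and technical groups. They were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 39 lists that had at least 3 measured genes. A list of lung, thymus and other neighbouring tissue genes had fewer at both ages and was not tested, with Scgb1a1 and Tg measured at 3 months and Tg alone at 12 months. List members were also adjusted over the list alone. Camera with an estimated correlation and fry, which tests whether the genes of a set move one way on balance, were run as alternatives.

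Named genes followed a rule set before the data were examined. It took Prdm16, then per age the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose higher group averaged at least 2 FPKM, leaving out symbols of the form Gm plus digits, ending in Rik or holding -ps, of which 20 were called at 3 months and 13 at 12 months. It also took the 2 to 4 members of lowest p from each described list, the genes called in both ages in the same direction, and the 10 genes of lowest p for a difference between ages, of which 1 is not reported here. Lrrc4b, Bcat2, Car11, Sln, Myl7, Bmp10, Sbk2, Clu, Rpl29 and Rps7 lie outside these ranks and were chosen after their values were seen.

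Depth was sought in the low values. At 12 months 88.6% to 90.7% of low values per library fell within 0.05 of a whole number of reads, at 21.7 to 31.2 M reads. Chance gives 10% at any 1 fixed setting, and more for the best of the depths and fragment lengths that were searched. At 3 months the share was 20.1% to 38.3%, so no depth was taken from it. An exact 0 can be a failed estimate in such files. Ryr2, an abundant cardiac channel gene, was listed at 0 in 1 library of 3 months and mt-Nd1 in 3, and 9 genes of 3 months and 30 of 12 months held an exact 0 while at least 0.5 of the libraries of that age held 10 FPKM or more. Some of these can be true absences, as for Eif2s3y in a 12-month control.

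The pipeline was tested on simulated data with 200 changed genes. Changes were added on the log2(FPKM + 1) scale, only to genes averaging above about 5 FPKM. For these gene tests the spread of each gene was drawn toward the median spread. The shares recovered therefore cover neither lower genes nor the full spread of the most variable ones. At 3 months (12200 genes) it recovered 37.3% of 1.5-fold, 89.6% of 2-fold and 100% of 4-fold changes, with 11 false calls. At 12 months (13179 genes) it recovered 0%, 20.9% and 92.4% with 5 false calls, and for the difference between ages (11580 genes) 1.49%, 43.3% and 98.5% with 5 false calls. Over 20 simulated sets without change, camera called 4 of 780 list tests at 3 months and 0 of 780 at 12 months. The simulated genes varied independently of each other, with the same spread in both labels. These counts therefore cannot show how camera fares where genes are correlated. They also cannot show how the tests fare where the labels differ in spread, as they did at 12 months.

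Alternatives set before the data were examined were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-of-ratios and TPM rescaling, the replicate number as a block, moderation without a trend, robust moderation, library weights, each library left out in turn, a 1.5-fold minimum, both ages in 1 fit and the other list tests. Added after seeing the data were exact 0 values as missing, protein-coding autosomal genes only, a covariate from Sln and Myl7, and the 2 nearly identical 12-month controls averaged and counted as 1. Where a library was left out of a pair at 12 months, the lone library was taken to vary like the others.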

Results

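RNA-seq measured transcript levels in dissected mouse hearts labelled control or Prdm16 knockout. Prdm16 encodes a zinc-finger transcriptional regulator best known for its part in brown fat. The series title names an age-dependent cardiac phenotype, so the design compares the 2 genotypes at each age and then the difference between labels across the ages. At 3 months there were 3 control and 3 knockout libraries, and at 12 months 2 control and 2 knockout libraries. Values were deposited as FPKM, a length- and depth-scaled expression unit, in 1 table per age. Summed FPKM ran from 516272 to 718787 per library at 3 months and from 890181 to 1171104 at 12 months. The low values at 12 months fell on steps of whole reads and gave depths of 29.6 and 31.2 M reads for the controls and 26.3 and 21.7 M reads for the knockout-labelled libraries. No such steps were found at 3 months, so that depth is unknown. Beyond the labels nothing says that libraries came from separate animals, so p-values measure the spread between these samples.

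Prdm16 itself, on chromosome 4 from 154316125 to 154636873 (minus strand, GRCm38), did not separate the labels at 3 months. Its mean was 1.76 ± 0.417 FPKM in the controls and 1.41 ± 0.635 in the knockout-labelled hearts (SD, n = 3 each). The library values were 1.44, 2.23 and 1.61 against 1.43, 0.760 and 2.03. The difference was −0.22 (SE 0.21, log2 scale), with a limma adjusted p (Benjamini-Hochberg) of 0.602. An exact two-sided permutation test gave p = 0.4, where 0.1 is the smallest p this design allows. At 12 months both knockout-labelled libraries (4.02 and 3.58 FPKM) lay below both controls (6.31 and 5.05), with means of 3.80 ± 0.309 and 5.68 ± 0.894 (SD, n = 2 each). This difference of −0.47 (SE 0.15) did not pass the test either (limma, Benjamini-Hochberg adjusted p = 0.340), and the exact two-sided permutation p was 0.333, the smallest possible. A gene-level value can include exons outside a deleted part, so it checks the labels only weakly, and directions below refer to the libraries as labelled.

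**Figure D1:**
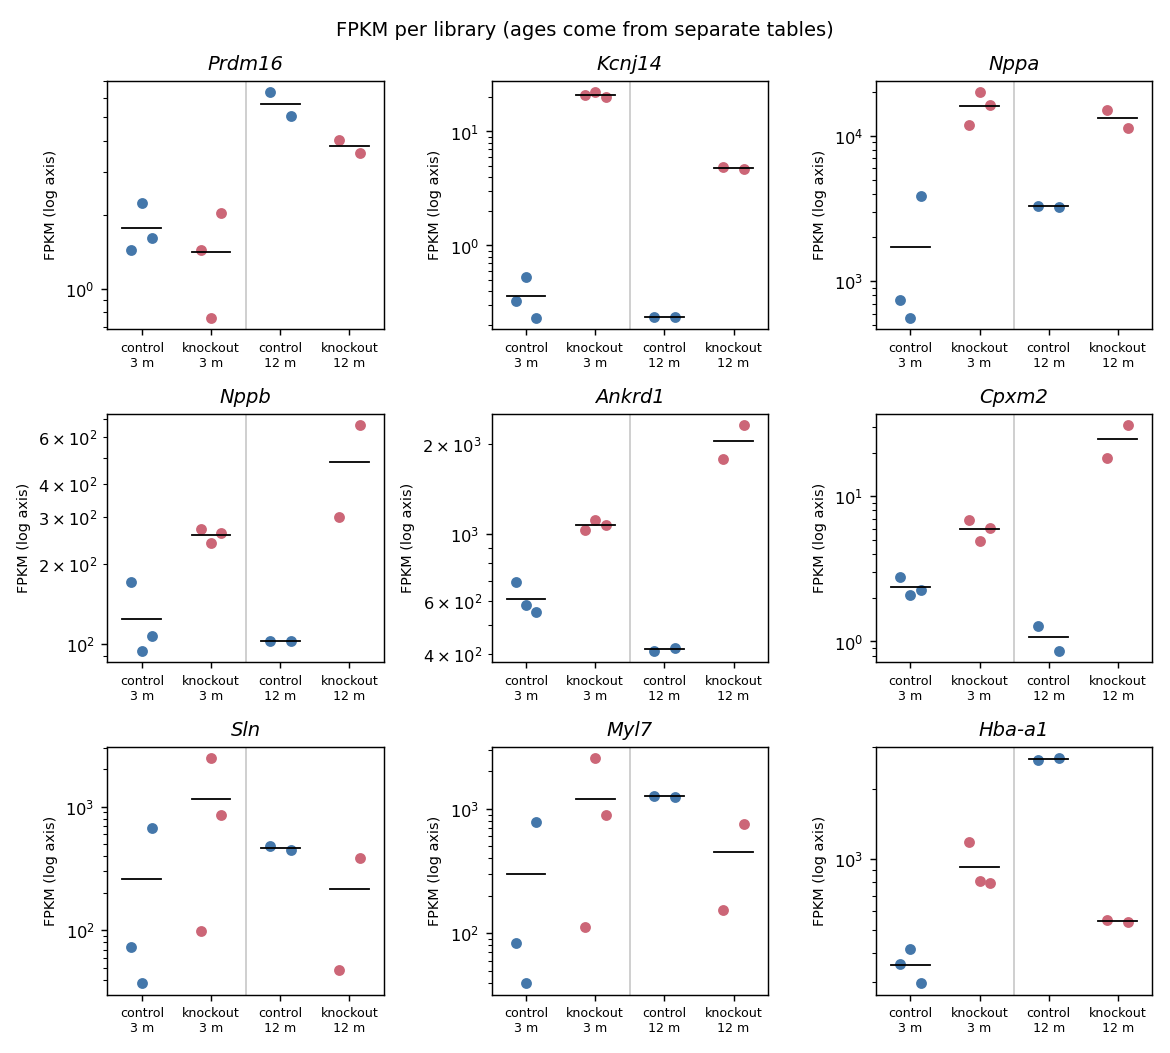
FPKM per library on log axes for 9 genes, with control libraries in blue, knockout-labelled libraries in red and a black line at each group mean; the ages come from separately made tables. Kcnj14 stood at 0.232 to 0.525 FPKM in the 3-month controls and at 20.1 to 22.0 in the knockout-labelled libraries, while Prdm16 overlapped between the labels at 3 months.

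At 3 months the largest rise was that of Kcnj14, which encodes an inwardly rectifying potassium channel subunit. It stood at 0.362 ± 0.149 FPKM in controls and 21.1 ± 0.974 in knockout-labelled hearts (SD, n = 3 each), a log2 difference of 4.02 (SE 0.12; limma, Benjamini-Hochberg adjusted p = 2.17e-06). Nppa, the precursor of atrial natriuretic peptide, rose from 1712 ± 1833 to 15967 ± 4019.7 FPKM (SD, n = 3 each), a log2 difference of 3.74 (SE 0.62; limma, Benjamini-Hochberg adjusted p = 0.0402). The Nppa call was lost in 8 of 19 alternatives (limma adjusted p from 3.85e-06 to 0.207), among them without control replicate 1 or 2, without knockout replicate 2 or 3, and after median-of-ratios rescaling. Over these alternatives the Nppa log2 difference ran from 2.83 to 4.59. Ankrd1, a stress-responsive muscle ankyrin repeat protein, rose from 610 ± 76.0 to 1073 ± 40.9 FPKM (log2 0.82, SE 0.14), a call that was lost when any 1 of the 6 libraries was left out. The other large rises were those of Nrtn (1.85), a neurotrophic ligand, the kallikrein Klk1b22 (1.84), the myosin light chain Myl1 (1.83), Lypd2 (1.80), the immunoglobulin A constant region Igha (1.74), the scaffold protein gene Ush1c (1.63), the cytotoxic granule gene Nkg7 (1.62) and the fatty acid desaturase Scd4 (1.51). Of these calls, those of Nrtn and Igha were lost when any 1 of the 3 controls was left out, that of Lypd2 also without knockout replicate 2, that of Myl1 without control replicate 1 or 2 or knockout replicate 2 or 3, and those of Nkg7 and Scd4 without control replicate 2 or 3. All these values are on the log2(FPKM + 1) scale, which understates changes of low genes.

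Among the falls at 3 months were those of Scgb1a1 (−3.71) and Bpifa1 (−1.99), secretory genes of the airway lining. Scgb1a1 stood at 11.1, 26.8 and 10.6 FPKM in the controls and at 0.319 or less in the knockout-labelled libraries. Mthfd2, a mitochondrial folate enzyme, fell from 17.4 ± 3.96 to 1.91 ± 0.584 FPKM (SD, n = 3 each), a log2 difference of −2.65 (SE 0.20; limma, Benjamini-Hochberg adjusted p = 0.000982). Hddc3 fell from 24.9 ± 0.582 to 6.40 ± 0.0629 FPKM (log2 −1.81, SE 0.10). Cyp26b1, which degrades retinoic acid, fell from 3.57 ± 0.889 to 0.590 ± 0.0373 FPKM (log2 −1.51). Atf5, a transcription factor of the mitochondrial stress response, fell from 93.4 ± 14.0 to 39.3 ± 1.45 FPKM (log2 −1.22). The receptor kinase gene Ephb1 (−1.10), the mitochondrial tRNA-modifying enzyme gene Cdk5rap1 (−1.07), the ribosomal protein gene Rplp0 (−0.86) and the zinc-finger gene Zfp945 (−0.80) also fell. The Ephb1 call was lost when any 1 control or knockout replicate 2 or 3 was left out, and those of Rplp0 and Zfp945 when any 1 control or knockout replicate 1 or 3 was. Kcnj14, Klk1b22, Mthfd2 and Hddc3 were the named 3-month calls that passed under every alternative that gave a value for them.

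In total 91 of 12200 genes passed at 3 months (limma, Benjamini-Hochberg adjusted p under 0.05), 76 higher and 15 lower in the knockout-labelled hearts. The groups did not overlap in any of the 91, while 24.7% of all tested genes were apart, against 10% by chance. Median-of-ratios rescaling gave 59 calls (42 higher, 17 lower) and TPM 134 (106 higher, 28 lower), of which 70 were among the 91. Without control replicate 2 the count was 22, without control replicate 3 it was 29, and without knockout replicate 2 it was 59. Of the 91, 14 were processed pseudogenes, whose values can share reads with their parent genes, as those of near-identical globin genes can. Of the named calls, Kcnj14, Klk1b22, Ush1c, Nkg7 and Atf5 lie with Lrrc4b (1.48), Bcat2 (0.94) and Car11 (0.92) within chromosome 7 from 43437073 to 46238503. These 8 calls were among 76 tested genes of that stretch, which was singled out after its values were seen.

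**Figure D2:**
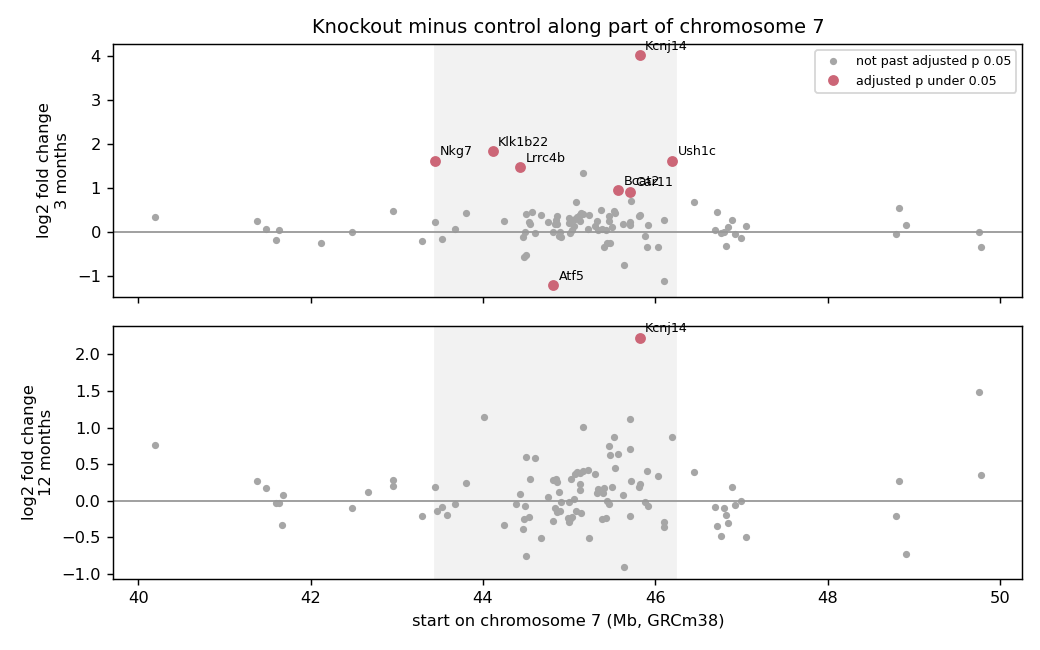
Log2 fold changes (knockout minus control) of tested genes by start position on chromosome 7 (Mb, GRCm38), at 3 months above and 12 months below, with genes past an adjusted p of 0.05 in red and the stretch with 8 calls shaded. At 3 months 7 of the 8 lay above 0 and Atf5 lay below, and of these 8 Kcnj14 was the 1 called at 12 months.

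Among the gene lists at 3 months, the 36 measured nuclear genes of respiratory complex I were all higher in the knockout-labelled hearts, with a median log2 difference of 0.40. They passed as a list (camera, Benjamini-Hochberg adjusted p = 1.06e-06), although none of them passed alone, over all genes or adjusted over the list alone. Ndufa13 averaged 250.4 ± 14.2 and 387 ± 68.1 FPKM and Ndufa11 62.9 ± 6.66 and 92.0 ± 12.6 FPKM (controls, then knockout-labelled; SD, n = 3 each). Knockout replicate 2 stood apart from the other 2 knockout-labelled libraries (robust SD of the log2 ratio 0.295 and 0.337, against 0.121 between those 2) and had the highest Ndufa13 (466 FPKM, against 345 and 352). By the same measure knockout replicates 1 and 3 were closer to control replicates 1 and 3 (0.187 to 0.228) than to knockout replicate 2. Control replicates 1 and 2 were 0.302 apart, so the libraries did not all group by label. Without knockout replicate 2 the respiratory complex I list at 3 months had a median of 0.29 and still passed. Respiratory complex IV (13 of 13 higher, median 0.40, camera adjusted p = 0.00234) and ATP synthase (16 of 17 higher, median 0.32, camera adjusted p = 0.00389) passed upwards as well. Their leading members were Cox7c (0.56) and Cox8b (0.56), subunits of cytochrome oxidase, and Atp5e (0.85) and Atp5h (0.61), none past the gene test. The TCA cycle list passed downwards (14 of 22 lower, median −0.13, camera adjusted p = 0.00526), led by Dlat (−0.43) and citrate synthase Cs (−0.39). The all-gene median was 0.09 at 3 months, and after median-of-ratios and TPM rescaling the TCA cycle median was −0.23 with each, that of ATP synthase 0.21 with each and that of the stress response −0.30 with each. The integrated and mitochondrial stress response list fell (14 of 21 lower, median −0.19, camera adjusted p = 6.98e-06), with Mthfd2 and Atf5 past the gene test and 5 members past it when adjusted over the list alone. Its amino acid synthesis genes Asns (−1.02) and Phgdh (−0.75) did not pass over all genes. With an estimated correlation none of these 5 lists passed, with adjusted p = 0.841 for the stress response and adjusted p = 0.917 for the others, and the lowest adjusted p of fry over all lists was 0.0975. Without control replicate 2 complex IV and ATP synthase no longer passed, and without control replicate 1 the TCA cycle did not.

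Markers of other cell types moved with the 3-month labels too. Red blood cell markers were higher in all 7 measured genes (median 1.28, camera, Benjamini-Hochberg adjusted p = 1.39e-06), and 5 of them rose in the gene test, 6 when adjusted over the list alone. Hba-a1, a haemoglobin alpha chain, rose from 355 ± 58.5 to 928 ± 222 FPKM and Hbb-bs from 519 ± 110.3 to 1264 ± 282 FPKM (SD, n = 3 each), with the first call lost when any 1 control was left out and the second without control replicate 2 or 3 or knockout replicate 1. Lymphocyte and neutrophil markers were higher in 10 of 10 genes (median 0.73, camera adjusted p = 2.20e-06), with Nkg7 and Gzma past the gene test (Gzma not when a control or knockout replicate 2 or 3 was left out) and 8 past it when adjusted over the list alone. Atrial markers were higher in 14 of 15 genes (median 1.95, camera adjusted p = 0.000233), with Nppa past the gene test and 5 past it when adjusted over the list alone, followed by Stard10 (2.18) and Fgf12 (2.30). The atrial genes Sln and Myl7 ranged widely within each label, Sln from 37.3 to 670.2 FPKM in controls and from 98.6 to 2473 in knockout-labelled libraries. Interferon response genes (26 of 27 higher, median 0.37, camera adjusted p = 0.0143, none past the gene test or over the list alone) and skeletal muscle markers (4 of 4 higher, median 0.87, camera adjusted p = 0.0258, 0 past the gene test and 3 over the list alone) passed as lists, led by Psmb9 (0.78) and H2-K1 (0.50), of antigen presentation, and by Casq1 (0.93) and Tnni2 (0.81). With an estimated correlation none of these 5 lists passed, with adjusted p = 0.841 or, for the atrial and interferon lists, adjusted p = 0.917. Without control replicate 2 the atrial, interferon and skeletal muscle lists no longer passed, the interferon list also not without control replicate 3 or knockout replicate 2, and the skeletal muscle list also not without knockout replicate 3. At a mean of at least 5 FPKM the lymphocyte and neutrophil and the interferon lists no longer passed, and without a filter the skeletal muscle list did not.

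In all, 10 of 39 lists passed at 3 months, 8 upwards and 2 downwards. With an estimated correlation camera passed 0 (lowest adjusted p = 0.841) and fry 0, and 4 of the 9 other ways to split these libraries into 3 and 3 passed 12 to 17 lists. The fetal and stress gene list did not pass (10 of 13 higher, camera, Benjamini-Hochberg adjusted p = 0.0565), although Nppa and Ankrd1 passed singly and 4 members passed when adjusted over the list alone. With the replicate number as a block that list did pass (camera adjusted p = 0.0352). Its members Nppb, the precursor of brain natriuretic peptide (124 ± 41.2 and 258 ± 15.8 FPKM, SD, n = 3 each), and Myh7, the slow myosin heavy chain (7.87 ± 2.58 and 16.1 ± 3.91 FPKM), did not pass over all genes. In the conduction and trabecular list Cntn2, a marker of the conduction system, rose from 1.34 ± 0.111 to 5.39 ± 1.66 FPKM with Nppa, while the list did not pass (camera adjusted p = 0.663). The extracellular matrix, sarcomere, calcium handling and ion channel, fatty acid, glycolysis, mitochondrial dynamics, mitochondrially encoded, complexes II and III, brown fat, PRDM16 partner, compact myocardium, TGF-beta and BMP, antioxidant, immediate early, circadian clock, cell cycle, histone, sex-linked, cardiomyocyte, fibroblast, endothelial, endocardial, smooth muscle and pericyte, macrophage, adipocyte, epicardial, and nerve and glia lists had camera adjusted p from 0.0657 to 0.975. In 15 of the lists that did not pass, the median, the mean and the test differed in sign.

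**Figure D3:**
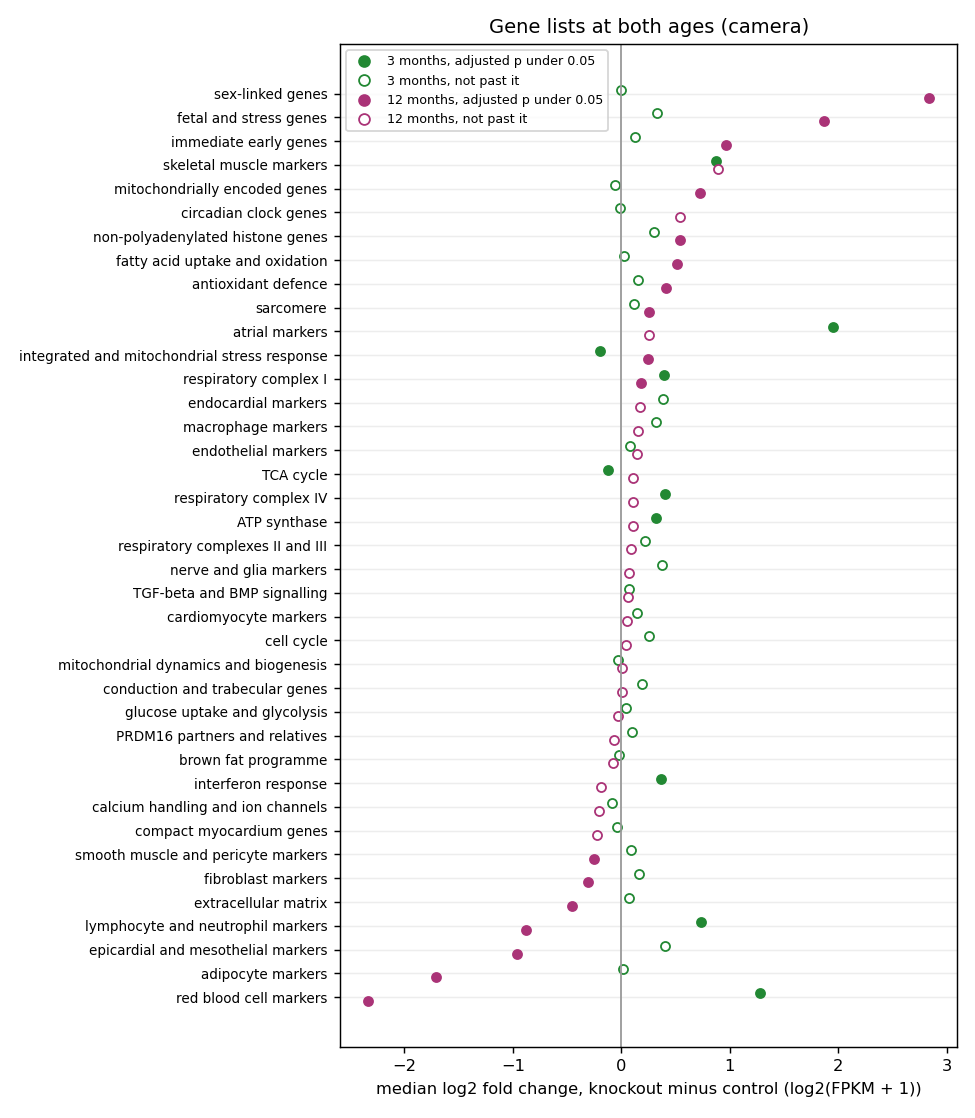
Median log2 fold change (knockout minus control, log2(FPKM + 1) scale) of each tested gene list at 3 months (green) and 12 months (purple), filled where the camera adjusted p was under 0.05 and open where it was not. Red blood cell markers lay at 1.28 at 3 months and −2.33 at 12 months, and with an estimated correlation no list passed at either age.

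At 12 months the groups differed first in sex-linked genes. Xist, the RNA that coats the inactive X chromosome, fell from 32.1 ± 1.45 FPKM in controls to 0.0575 ± 0.0475 in knockout-labelled hearts (SD, n = 2 each), a log2 difference of −4.97 (SE 0.12; limma, Benjamini-Hochberg adjusted p = 0.00617). The Y-linked genes Ddx3y (log2 4.52), Uty (2.84) and Kdm5d (2.63) rose, and Eif2s3y (5.19) rose from 0 and 0.0847 FPKM to 34.3 and 40.1. In all 6 libraries of 3 months Xist stood at 0.490 FPKM or less and Ddx3y at 16.5 or more. Genotype and sex-linked expression therefore cannot be separated in any 12-month difference given here.

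**Figure D4:**
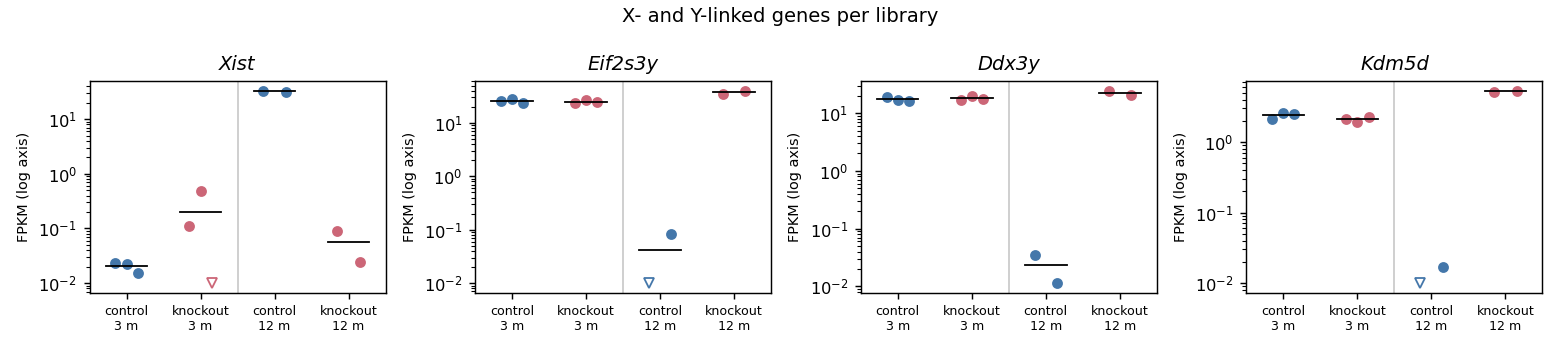
FPKM per library on log axes for Xist and 3 Y-linked genes, with controls in blue, knockout-labelled libraries in red and black lines at group means of at least 0.01; open triangles mark values under 0.01 FPKM, drawn at 0.01. At 12 months Xist stood at 31.0 or more in controls and 0.0911 or less in knockout-labelled libraries, and Ddx3y at 0.0352 or less and 20.7 or more.

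Outside the sex chromosomes, stress-related cardiac genes were among the rises at 12 months. Ankrd1 rose from 414 ± 6.31 to 2049.9 ± 372 FPKM (SD, n = 2 each), a log2 difference of 2.29 (SE 0.17; limma, Benjamini-Hochberg adjusted p = 0.0449). Atf3, a stress-induced transcription factor, rose from 2.08 ± 0.348 to 14.0 ± 2.15 FPKM, and Acta1, skeletal alpha-actin, from 129 ± 2.41 to 433 ± 32.1 FPKM (log2 1.73). Acta1 was not analysed at 3 months. Cpxm2, a carboxypeptidase-like secreted protein, rose from 1.07 ± 0.286 to 24.7 ± 8.86 FPKM (log2 3.60; limma, Benjamini-Hochberg adjusted p = 0.0498), and the complement component C7 from 1.22 ± 0.00377 to 13.3 ± 0.911 FPKM (log2 2.68). The short RNAs AL596185.1 (25.0 and 30.5 FPKM) and Snora68 (15.8 and 19.3 FPKM) were listed at 0 in both controls.

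Single genes fell at 12 months as well. Scd1, a fatty acid desaturase, fell from 62.9 ± 0.505 to 5.44 ± 0.0659 FPKM (SD, n = 2 each), a log2 difference of −3.31 (SE 0.10; limma, Benjamini-Hochberg adjusted p = 0.00617). Kcne1, a potassium channel accessory subunit, fell from 24.1 ± 1.11 to 1.70 ± 0.743 FPKM (log2 −3.25), Car3, an adipocyte-rich carbonic anhydrase, from 30.9 ± 1.55 to 3.33 ± 0.0557 (−2.88), and Eln, elastin, from 68.8 ± 0.718 to 9.93 ± 0.0220 (−2.68). Ucp1, the uncoupling protein of brown fat, stood at 8.80 and 8.01 FPKM in the controls and was listed at 0 in both knockout-labelled libraries. Mir6363 (64.1 and 134 FPKM in the controls), Rny1 (102 and 48.4), Snora31 (14.8 and 14.1) and Snhg9 (6.78 and 8.62) were likewise listed at 0 in both knockout-labelled libraries. An exact 0 can be a failed estimate or a true absence, which these values do not separate.

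In total 52 of 13179 genes passed at 12 months (limma, Benjamini-Hochberg adjusted p under 0.05), 22 higher and 30 lower, of which 7 lay on sex chromosomes and 14 belonged to classes of small non-coding RNA. The groups did not overlap in any of the 52, while 50.3% of all tested genes were apart, against 33.3% by chance. Rescaling to TPM gave 47 calls (14 higher, 33 lower) and moved the median of all genes from 0.01 to −0.27, since the summed FPKM of both knockout-labelled libraries was higher than that of both controls. The 2 controls were far closer to each other (robust SD of the log2 ratio 0.092 over genes of 10 FPKM or more) than the 2 knockout-labelled libraries were (0.407). By the same measure knockout replicate 1 was closer to both controls (0.255 and 0.245) than to knockout replicate 2. Knockout replicate 2 stood at 0.436 and 0.446 from the controls. Over genes of 100 to 1000 reads the median chi-square between the controls was 1.04 times that of counting noise, against 7.03 to 12.2 for the other pairs, although the chi-square test over genes still found a difference (p = 9.88e-13). With the controls averaged and counted as 1, limma called 0 genes (414 at an unadjusted p under 0.05). Without control replicate 1 or 2 it also called 0 (440 and 437), without knockout replicate 1 it called 4409, and without knockout replicate 2 it called 654, so the count rests on the closeness of the controls.

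Of 39 lists, 17 passed at 12 months, 10 upwards and 7 downwards, and sex-linked genes were one of them (camera, Benjamini-Hochberg adjusted p = 0.000388). The fetal and stress genes were higher in 13 of 14 (median 1.86, camera adjusted p = 1.27e-07), with Acta1 and Ankrd1 past the gene test and 10 past it when adjusted over the list alone. Nppa stood at 3273 ± 55.3 and 13184 ± 2716 FPKM (SD, n = 2 each; log2 1.99, limma, Benjamini-Hochberg adjusted p = 0.0759). Immediate early genes were higher in 18 of 19 (median 0.96, camera adjusted p = 1.89e-09), with Atf3 past the gene test and 12 past it when adjusted over the list alone, Junb among their leading members at 5.33 ± 0.164 and 10.4 ± 0.0723 FPKM. Integrated and mitochondrial stress response genes were higher in 20 of 22 (median 0.25, and −0.01 after TPM rescaling; camera adjusted p = 0.00171, Atf3 past the gene test and 3 adjusted over the list alone), with Chac1 (1.33) and Ddit3 (0.78) following. With an estimated correlation the adjusted p was 0.439 for each of these 4 lists.

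Several lists passed upwards at 12 months without single calls over all genes, while other metabolic lists did not pass. Fatty acid uptake and oxidation genes were higher in 38 of 39 (median 0.51, camera, Benjamini-Hochberg adjusted p = 1.30e-06), with Cpt2, a mitochondrial acylcarnitine transferase, at 107 ± 1.35 and 160.2 ± 16.3 FPKM (SD, n = 2 each) and the uncoupling protein Ucp3 at 9.45 ± 0.0264 and 36.6 ± 13.5. Antioxidant genes were higher in 28 of 30 (median 0.42, camera adjusted p = 1.33e-06) and mitochondrially encoded genes in 8 of 8 (median 0.72, camera adjusted p = 0.000216). Nfe2l2 (0.62), a regulator of antioxidant genes, and Gsta3 (1.06) led the former, mt-Nd1 (0.80) and mt-Nd4 (0.73) the latter. After TPM rescaling the medians were 0.21 for fatty acid, 0.11 for antioxidant, 0.40 for mitochondrially encoded and 0.28 for histone genes. Adjusted over the list alone, 5 mitochondrially encoded genes passed and none of the fatty acid or antioxidant genes did. Complex I genes were higher in 34 of 36 (median 0.18, and −0.14 after TPM rescaling; camera adjusted p = 0.000818), sarcomere genes in 20 of 27 (0.26, and −0.07 after TPM rescaling; camera adjusted p = 0.00420) and histone genes in 7 of 7 (0.54, camera adjusted p = 0.0441), with 2 sarcomere genes and none of the others past the gene test when adjusted over the list alone. The histone list holds non-polyadenylated genes and is 1 of the technical lists. The leading members were Ndufa10 (0.32, with Ndufa10 at 12 months at −0.0089 after TPM rescaling) and Ndufa5 (0.41), Lmod2 (0.94) and Tcap (1.17), and Hist1h4i (0.88) and Hist1h2bc (0.62). These medians lay above the all-gene median after TPM rescaling as well, where complex I no longer passed. At a mean of at least 5 FPKM the sarcomere and histone lists no longer passed. Without a filter the histone and mitochondrially encoded lists did not pass. Complex I and histone genes did not pass without knockout replicate 2. With an estimated correlation these 6 lists had adjusted p = 0.439 to adjusted p = 0.754.

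Markers of red blood cells and fat fell most among the 12-month lists. Red blood cell markers were lower in 7 of 7 (median −2.33, camera, Benjamini-Hochberg adjusted p = 1.82e-13), 6 past the gene test and 7 adjusted over the list alone, with Hba-a1 falling from 2683 ± 32.7 to 543 ± 7.98 FPKM (SD, n = 2 each). Adipocyte markers were lower in 9 of 11 (median −1.70, camera adjusted p = 1.89e-09), with Car3, Ucp1 and Plin1 past the gene test and 9 adjusted over the list alone. Extracellular matrix genes were lower in 32 of 50 (median −0.46, camera adjusted p = 0.00171). Among them Eln and Col6a3 fell and Timp4, a metalloproteinase inhibitor, rose, while 17 were lower and 6 higher when adjusted over the list alone. Col3a1, a fibrillar collagen, stood at 397 ± 7.28 and 115 ± 34.9 FPKM and did not pass over all genes. Fibroblast (12 of 16 lower, camera adjusted p = 0.00362), lymphocyte and neutrophil (8 of 10, 0.00538), epicardial (7 of 8, 0.0222) and smooth muscle and pericyte markers (11 of 13, 0.0480) were lower as lists, with no member past the gene test over all genes and 2, 3 (with 1 higher), 0 and 1 lower when adjusted over the list alone. They were led by Col3a1 and Lum (−0.67), Ighm (−1.07) and Cd79b (−1.02), Msln (−1.56) and Lrrn4 (−1.09), and Acta2 (−0.94), with Des (0.72) higher. With an estimated correlation no 12-month list passed, these 7 having adjusted p = 0.439 to adjusted p = 0.679, and fry called 9 lists. Of the 17 lists these were the red blood cell, adipocyte, mitochondrially encoded, sex-linked, fibroblast, sarcomere and smooth muscle lists, and the other 10 did not pass with fry. The other 2 that fry called, skeletal muscle and brown fat, did not pass with camera.

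After TPM rescaling the matrix, lymphocyte, epicardial and smooth muscle lists no longer passed at 12 months, and the medians of the matrix, fibroblast and smooth muscle lists moved with all genes, from −0.46 to −0.75, from −0.31 to −0.60 and from −0.25 to −0.53. At a mean of at least 5 FPKM the lymphocyte, epicardial and sex-linked lists no longer passed, and without a filter the smooth muscle list did not. The smooth muscle list also did not pass when any 1 of the 4 libraries was left out, and the lymphocyte and epicardial lists not without knockout replicate 1. The atrial, skeletal muscle, calcium handling and ion channel, TCA cycle, complex IV, complexes II and III, ATP synthase, glycolysis, mitochondrial dynamics, brown fat, PRDM16 partner, conduction, compact myocardium, TGF-beta and BMP, circadian clock, interferon, cell cycle, cardiomyocyte, endothelial, endocardial, macrophage, and nerve and glia lists did not pass (camera, Benjamini-Hochberg adjusted p from 0.0734 to 0.994). The median, mean and test differed in sign in 4 of these. The members Kcne1 (calcium handling and ion channel and conduction lists), Ucp1 (brown fat), Acta1 (skeletal muscle) and Ankrd1 (compact myocardium) passed singly. In the atrial list, where Nppa did not pass either, Sln (464 ± 23.4 and 217 ± 239 FPKM) and Myl7 (1260 ± 21.7 and 451 ± 422 FPKM, SD, n = 2 each) did not pass.

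The difference between the labels was unlike at the 2 ages in 160 of 11580 genes tested at both (limma interaction contrast, Benjamini-Hochberg adjusted p under 0.05), 76 with a more positive difference at 12 months and 84 with a more negative one. Because the 12-month labels also differ in sex-linked genes and the 3-month labels do not, this contrast tests genotype together with sex. The ages also differ in table and library preparation, which the contrast does not separate from age. The 4 Y-linked genes Eif2s3y (5.25), Ddx3y (4.46), Uty (2.80) and Kdm5d (2.76) had the lowest p (log2 differences, 12 months minus 3 months). Also among the lowest p were the globin genes Hba-a2 (−3.87), Hbb-bs (−3.71), Hba-a1 (−3.67) and Hbb-bt (−3.59), and 8430408G22Rik (2.03). Median-of-ratios rescaling gave 213 calls (132 higher, 81 lower) and TPM 122 (33 higher, 89 lower). With the 12-month controls averaged and counted as 1 there were 40, without 12-month control replicate 1 or 2 there were 40 and 41, and without knockout replicate 1 or 2 of 12 months there were 787 and 350. Leaving out 3-month libraries gave 102 and 92 without control replicates 1 and 2 and 83 and 93 without knockout replicates 1 and 3.

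Across the 11580 genes the fold changes at both ages were weakly related (Pearson r = 0.116, Spearman rho = 0.142, across genes, which are not independent replicates). Without knockout replicate 2 of 12 months r was −0.0444, and without knockout replicate 1 it was 0.206. Of the 75 genes called at 3 months and tested at 12 months, 45 (60%) kept their sign, and of the 31 called at 12 months and tested at 3 months 14 (45.2%) did, against 55.5% of all genes. Called at both ages in the same direction were 3 genes, Kcnj14 (4.02 at 3 months and 2.23 at 12 months), Cpxm2 (1.04 and 3.60; the 3-month call lost without control replicate 2 or 3) and Ankrd1 (0.82 and 2.29), against 0.0925 expected of independent lists of higher genes. The 12-month calls of all 3 were lost without a filter. That of Cpxm2 was also lost after median-of-ratios rescaling and with robust moderation, and those of Kcnj14 and Ankrd1 with the replicate block. Called in opposite directions were 5, the globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt and the erythroid haem synthesis gene Alas2, all higher at 3 months and lower at 12 months. No expected number was worked out for opposite directions, so the 3 shared genes do not by themselves show that the ages agree. Without either 12-month control 0 genes were shared in direction, without knockout replicate 1 or 2 of 12 months 30 and 18, and without control replicate 2 or 3 of 3 months 1.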

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

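The tests of the explanations below, and the counts over other splits of the samples, were chosen only after the results were seen, and the test of the difference between ages was planned. The ages differ in table and library preparation, which a contrast between them does not separate from age. The difference between the labels was unlike at the 2 ages by a test of that contrast itself in 160 genes (limma, Benjamini-Hochberg adjusted p under 0.05), where genotype cannot be separated from sex because the 12-month labels differ in both. Among those with the lowest p were Eif2s3y (5.25), Ddx3y (4.46), Kdm5d (2.76), Uty (2.80), Hbb-bt (−3.59), Hba-a1 (−3.67), Hba-a2 (−3.87), Hbb-bs (−3.71) and 8430408G22Rik (2.03), as log2 differences of 12 months minus 3 months. For 8430408G22Rik the change was 0.36 at 3 months and 2.39 at 12 months. These named differences stayed past the threshold under every alternative that gave a value for them.

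The first pattern is the 12-month difference, in which 45 of the 52 called genes lie outside the sex chromosomes. A difference in sex between the groups cannot be told apart from genotype there, because every control held Xist at 31.0 FPKM or more and every knockout-labelled library held Ddx3y at 20.7 or more. All 6 libraries of 3 months were alike in Xist and Ddx3y. That argues against sex as the source of the 3-month differences of the 3 genes called at both ages in the same direction. The smallest was 0.82, of Ankrd1, a call lost when any 1 library was left out. These 3 genes were picked for being called at 3 months, so that they differ there is no test of sex. For their 12-month differences sex stays open. The number of 12-month calls may also come from a spread made too small by controls that differ little beyond counting noise, their median chi-square being 1.04 times that of counting noise, and limma called 0 genes with the controls averaged (414 at an unadjusted p under 0.05). Effects of genotype and of age remain open and untested beside these.

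The second pattern is the rise of Nppa and other atrial markers at 3 months, which could come from more atrial tissue in the knockout-labelled samples. With the Sln and Myl7 level of each library as a covariate, the Nppa difference was 2.83 (95% interval 1.89 to 3.77, limma, Benjamini-Hochberg adjusted p = 0.0247, in a range of 3.85e-06 to 0.207 over the alternatives), against 3.74 without it, which argues against the atrial share that Sln and Myl7 measure as the whole cause for Nppa. Sln (2.27) and Myl7 (2.20) differed between the labels too, without passing the gene test. A genotype effect shared by the atrial genes would therefore shrink with this covariate as well. The median of the 12 other measured atrial markers went from 1.41 to 0.44 with the covariate, as a varying atrial share predicts, but this drop does not separate it from such an effect. Among them Stard10 passed with the covariate (1.30, limma, Benjamini-Hochberg adjusted p = 0.0431), Fgf12 (1.39, adjusted p = 0.0905), Sbk2 (1.04, 0.327) and Clu (0.49, 0.429) did not pass, though their unadjusted intervals lay above 0, and Bmp10 went to −2.51. An atrial part that Sln and Myl7 do not follow, and a genotype effect on Nppa or on the other atrial markers, both remain open. Nppa (start 148000722) and Nppb (start 147985788) also lie on chromosome 4, as Prdm16 does (start 154316125). A strain segment linked to the modified allele was not tested for them.

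The third pattern is the closeness of 3-month calls on chromosome 7. A candidate explanation is a strain segment linked to a modified allele, which needs calls closer together than chance and an allele nearby, a condition added after the scan was seen, while Prdm16, the 1 modified gene the labels name, lies on chromosome 4, so the explanation stays open. The densest 3 Mb held 8 calls of separate families, where 10000 random sets of tested genes had a median of 3 and a highest of 7 (permutation p = 0.0001, the smallest they can give). That scan replaced a test of the members' 12-month direction, which had left the matter open, with 5 of 6 measured members in the same direction and 1, Atf5, opposite (0.28, not past the test). Over the whole genome 17 of the calls had a called neighbour within 1 Mb, against a mean of 12.2 in random sets (permutation p = 0.165), and with protein-coding genes alone 17 of 68 against 7.64 (permutation p = 0.0116), so this wider form is left open, a reading that was loosened from an exclusion after the first p was seen. The 17 include all 8 calls of the chromosome 7 stretch, so the wider form is not separate from that cluster.

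The 6 libraries of 3 months can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The real split called 91 genes and the highest of the others 1, so 1 of the 10 splits gave as many. For gene lists the real split called 10 and the highest of the others 17, and 5 of the 10 splits gave as many.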

How the results depend on the processing

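Added after the data were seen were the covariate, protein-coding, exact 0 and averaged-control settings, and the rest were planned. Without a filter 10 genes passed at 3 months, 17 at 12 months. Other 3-month counts were 59 with median-of-ratios rescaling, 29 with the replicate block, 165 with library weights and 57 with the Sln and Myl7 covariate, and leaving out 1 library gave 22 to 81. At 12 months 437 passed with both ages in 1 fit, 15 among protein-coding autosomal genes and 0 with the controls averaged (limma, 414 at an unadjusted p under 0.05), and leaving out 1 library gave 0 to 4409. For the difference between ages the counts were 55 with the replicate block, 40 with the controls averaged and 40 to 787 without 1 library. Lists went to 0 with an estimated correlation at both ages and to 0 and 9 with fry, and without 1 library to 6 to 16 at 3 months. The choice of filter also ended the calls of some lists at both ages. Genes shared in direction were 5 at pseudocount 0.1, 0 with the controls averaged and 0 to 30 without 1 library, and the correlation of fold changes at both ages ran from −0.0444 to 0.206 without 1 library. Mylpf at 3 months, not called, ran from −0.011 (without control replicate 2) to 0.39, and Ndufa10 at 12 months, not called, turned to −0.0089 with TPM. The cause was not tested.

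Prdm16 did not pass the gene test in any setting, and at a mean of 5 FPKM its 3-month value was not computed. Of 1110 alternatives for named genes at 3 months 947 left the outcome as it was, 129 weakened it, 33 strengthened it and 1 turned its sign, and of 1200 at 12 months these were 964, 141, 94 and 1. Only 27 of the 60 named genes at 3 months and 29 of the 78 at 12 months were calls. A gene that was not called and stayed so counts as left as it was. The 129 and 141 weakened outcomes all fell on the calls, so the pooled counts overstate how steady the calls were. The numbers gave no sign of pairing at 3 months. With the group mean of each gene subtracted, same-numbered libraries correlated there at −0.12, −0.46 and −0.14. Differently numbered ones ran from −0.33 to 0.37. At 12 months the value was −0.0063, but with 2 libraries per group the pairs can differ in sign alone, so it cannot decide. The replicate block is therefore not taken as a paired fit. At 12 months it called 40 genes.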

Other observations

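The genes set side by side here were chosen after the results were seen, while the gene test itself was planned. Airway genes were present in the 3-month controls. Scgb1a1 and Bpifa1 stood at up to 26.8 and 5.50 FPKM there and at 0.319 and 0.124 or less in the knockout-labelled libraries, and both were listed at 0 in all 4 libraries of 12 months.

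The difference between the labels was unlike at the 2 ages for Scd1 (−3.51, limma interaction, Benjamini-Hochberg adjusted p = 0.0168) and for Scd4 no difference passed (0.01, adjusted p = 0.995), though the 12-month labels also differ in sex and the ages in library preparation. Scd1 had a 3-month difference of 0.20 (limma, Benjamini-Hochberg adjusted p = 0.827) and a 12-month difference of −3.31 (0.00617). Scd4 had a 3-month difference of 1.51 (0.0104) and a 12-month difference of 1.52 (0.473), the latter with a spread of 29.6 FPKM (SD, n = 2) in the knockout-labelled hearts. Mthfd2 and Hddc3, which fell at 3 months, had 12-month differences of 0.25 and −0.58 that did not pass (limma, Benjamini-Hochberg adjusted p = 0.647 and 0.634).

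Single ribosomal protein genes were called both ways at 3 months, and ribosomal protein genes were not tested as a list. Rpl29 (1.40) and Rps7 (1.39) rose, and 14 processed pseudogenes were among the calls, while Rplp0 fell by 0.86. Their values can depend on how reads were shared among copies, which the sources used here do not give and which was not tested. At 12 months Bmp10, an atrial growth factor, stood at 56.7 ± 1.04 FPKM in controls and 12.7 ± 17.6 in knockout-labelled hearts (SD, n = 2 each), a difference that did not pass (limma, Benjamini-Hochberg adjusted p = 0.434).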
